A study of Homo sapiens with 4 samples.

How the data were processed

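The measurements were messenger RNA levels in HCT116, a human colon cancer cell line, in 4 samples that form a design of 2 lines by 2 treatments. The lines were unmodified cells, labelled wild type, and cells overexpressing human IDO1. Each was treated for 24 h with 1 mM indole or with DMF, the solvent control. Per the labels' protocols, RNA was isolated with a column kit and barcoded libraries were made with the AmpliSeq whole-transcriptome kit for Ion sequencers, which amplifies 1 short target per gene by PCR. Each deposited file holds raw counts of reads per amplicon target, with no normalization by the authors, per the file headers and the whole-number values. The genome build was hg19 per the submitters' processing notes. The aligner and the counting tool were not given in the sources used here.

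The series' design text states 2 replicates each, but each file has 1 count column. Whether a column is 1 replicate or a sum of replicates is not stated, so each group was treated as 1 library. The design fixed before the data were examined had a branch for this case, and the branch was chosen from the number of columns before any test. There were no replicates within a group, so no p-value was computed for a pair of groups.

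All 4 files list the same 20812 targets, and no row lacks a gene name. Library totals were 22673148 reads in wild type with DMF, 18283862 in wild type with indole, 22736172 in the IDO1 line with DMF and 19069730 in the IDO1 line with indole. A count of 0 was given the floor of 3 reads, which corresponds to between 0.131 and 0.157 CPM across libraries. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. Because each gene is read from 1 short target, a value says nothing of other parts of the transcript. Targets within histone, tubulin, ribosomal protein and other families of near-identical copies may share reads and are uncertain.

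Counts were scaled by TMM over all 4 libraries to CPM. For each of the 4 pairwise comparisons, the log2 ratio of CPM plus a pseudocount of 1 was computed for genes with at least 10 CPM in at least 1 of the 2 libraries, and genes at least 2-fold apart on that scale were counted. The pseudocount understates the change of low genes. Folds of named genes are ratios of scaled CPM without a pseudocount, with exact 95% Clopper-Pearson intervals from the split of reads between the 2 libraries. Such an interval compares 2 libraries, not 2 conditions. Against a library with 0 reads, the fold is a lower bound against the floor of 3 reads.

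In the 2 additive fits, the raw counts of all 4 libraries were modelled on line and treatment with edgeR's quasi-likelihood test after filterByExpr, with Benjamini-Hochberg adjustment at 0.05. The standard error (SE) given with a log2 fold change was back-calculated as its absolute value over the square root of the test's F statistic. It is approximate and was not estimated by the fit itself. Each factor then has its 2 libraries per level from the other factor's levels, and 1 residual degree of freedom is left. That residual is the interaction plus library noise, so a gene whose indole response differs between lines tests as noisier. Nothing says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

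The 32 gene lists, holding 557 genes, were fixed before the data were examined. They cover targets of the aryl hydrocarbon receptor (AHR) and of the pregnane X receptor (PXR), tryptophan metabolism, stress and metabolic pathways, cell cycle, differentiation, and markers of leukocytes, fibroblasts, endothelial cells, and hepatocyte and erythroid cells. A list with at least 3 measured genes was described by its median log2 ratio and by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the central 95% of random lists is said to stand apart. This describes these libraries and is not a test. On the additive fits, limma's camera was run with a preset correlation of 0.01 and with an estimated one, and fry was run as well, each adjusted over 28 lists. With 1 residual degree of freedom, the estimated correlation rests on a single residual contrast.

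The genes named were chosen by a rule written before the data were examined. It takes IDO1 first, and the 10 largest differences in each direction for each pairwise comparison and each additive effect, the latter among genes past the threshold. It adds the 4 members with the largest difference of each list that stands apart, and all measured AHR targets and genes of tryptophan metabolism. Genes outside it are said to have been chosen after their values were seen. The text names 16 sex-linked genes nowhere, although they stay in all counts. The alternatives were library totals, median-of-ratios size factors, pseudocounts of 0.25 and 5, minimums of 1 and 50 CPM, totals without the 10 most abundant genes, DESeq2, limma-trend, other filters and a fit without the second factor. The 3 more named under the dependence on processing were chosen after seeing the data.

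The code was tested on simulated counts with known changes, drawn with the fitted dispersion for the additive fits and with counting error alone for the pairwise counts. Changes were planted only in genes with a mean of at least 10 CPM, with the same dispersion for all genes and no interaction. The recovery below therefore does not describe lower genes, or genes whose indole response differs between lines. In the additive fit for line, 58.2% of 67 planted 2-fold changes and 100% of the 4-fold and 8-fold changes were recovered, with 7 false calls among 13049 genes tested. For treatment, 55.2% of the 2-fold changes were recovered and 100% of the larger ones, with 12 false calls among 13038 genes. In the pairwise comparison of indole with DMF in wild type, the 2-fold count recovered 37.3% of planted 2-fold changes and 100% of the larger ones. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Transcript GC content and length came from another genome build, matched by gene symbol for 93.6% of the genes compared in wild type, and no coordinates are given.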

Results

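Messenger RNA levels were measured in HCT116 human colon cancer cells by amplicon sequencing, with 1 short PCR target for each of 20812 genes. Indole is a product of bacterial tryptophan breakdown. IDO1 is the enzyme that opens the tryptophan ring on the way to kynurenine. The 4 groups were wild type cells and cells overexpressing human IDO1, each with DMF or with 1 mM indole for 24 h. Each group was represented by 1 library, and there were no replicates within a group. Totals ranged from 18283862 reads in wild type with indole to 22736172 in the IDO1 line with DMF. Between 14892 and 15505 targets had reads, and the 10 most abundant genes took 10.5% to 11.9% of them. The intervals given with folds are 95% intervals of counting error only.

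IDO1 had 0 reads in wild type with DMF and 2 in wild type with indole, against 3451 and 2440 in the IDO1 line with DMF and with indole. It was at least 1072-fold higher in the IDO1 line in DMF, and 1234-fold higher in indole (341 to 10192). The labels and the level of the targeted gene thus went the same way in all 4 libraries. IDO2, the paralog of IDO1, had 0 reads in both wild type libraries and 317 and 253 in the IDO1 line, which is 9.19% and 10.4% of the IDO1 reads. Reads of these paralogs may be shared, so the IDO2 value is uncertain.

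The first comparison asked how wild type cells respond to indole. Genes of mitosis and of cholesterol synthesis were lower with indole, and genes of the ATF4 amino acid stress response were higher. Of 21 measured mitosis genes, 0 were higher and 12 were at least 2-fold lower, with a median log2 ratio of -1.09. Among them were BIRC5, a survival and chromosome passenger protein, 2.54-fold lower (2.43 to 2.64), the mitotic cyclin CCNB1, 2.51-fold lower (2.33 to 2.71), and CDC20, an activator of the anaphase-promoting complex, 2.42-fold lower (2.29 to 2.55). Of 21 cholesterol synthesis genes, 11 were at least 2-fold lower and 0 higher, with a median of -1.02. ACAT2, which makes acetoacetyl-CoA, was 3.49-fold lower (3.09 to 3.96). The mevalonate pathway enzymes MVD and HMGCS1 were 2.74-fold (2.63 to 2.85) and 2.72-fold (2.57 to 2.88) lower. Both lists lay at percentile 0 of the matched random lists.

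Other groups that were lower with indole in wild type were DNA replication, with a median log2 ratio of -0.60 over 22 genes, and fatty acid synthesis, with -0.61 over 10 genes. TYMS, which makes thymidylate, was 2.22-fold lower (2.15 to 2.29) and FASN, the fatty acid synthase, 2.42-fold lower (2.38 to 2.46). The nuclear OXPHOS list had a median of -0.54, the proteasome list -0.47 and the ribosome biogenesis list -0.44. Removal of the trend with abundance, GC content and length gave -0.34, -0.30 and -0.21 for these, and -0.47 for DNA replication. With a pseudocount of 5 the ribosome biogenesis list no longer stood apart. Hypoxia and glycolysis genes had a median of -0.57, and HK2, a hexokinase, was 1.95-fold lower (1.76 to 2.18). NDRG1, a hypoxia-inducible gene on that list, was 2.14-fold higher (2.05 to 2.22). Library totals gave medians of -0.37 for hypoxia and glycolysis, -0.43 for DNA replication, -0.44 for fatty acid synthesis, -0.37 for nuclear OXPHOS, -0.30 for the proteasome and -0.27 for ribosome biogenesis.

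On the higher side, the ATF4 list had a median of 0.62 over 20 genes, of which 18 were above 0 and 3 at least 2-fold higher. CHAC1, which degrades glutathione, was 4.50-fold higher (4.03 to 5.02), and GDF15, a stress-induced secreted factor, 4.13-fold higher (4.03 to 4.25). SLC7A11, the cystine transporter subunit, was 2.54-fold higher (2.40 to 2.70). The interferon response list had a median of 0.47 over 13 genes, and its member GBP2, a guanylate-binding protein, was 4.98-fold higher (3.59 to 7.04). The p53 target list had a median of 0.37 over 20 genes, with TP53INP1 2.66-fold higher (2.29 to 3.10), and the autophagy and lysosome list 0.44 with GABARAPL1 1.91-fold higher (1.68 to 2.19). Epithelial junction genes had a median of 0.29, with the tight junction scaffold TJP1 3.25-fold higher (2.58 to 4.13), and ER unfolded protein response genes a median of 0.19. With library totals these lists kept their direction and stood apart, with medians of 0.37 for the ER list, 0.46 for junctions, 0.80 for ATF4, 0.63 for interferon, 0.55 for p53 and 0.62 for autophagy. In all, 16 of 25 lists stood apart from random lists, where lists of unrelated genes would give 1.25. Genes of a list can move together, so the excess is not a test.

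AHR is the ligand-activated receptor of indoles and dioxins, and some of its targets were higher with indole in wild type while others were not. The 3 genes with the largest folds upward were under 10 CPM in every library. CYP1A1, its classical target enzyme, went from 18 to 91 reads, 5.56-fold higher (3.33 to 9.79). CYP1B1 went from 25 to 87 reads, 3.82-fold higher (2.43 to 6.23), and AHRR, the receptor's repressor, from 40 to 141 reads, 3.87-fold higher (2.71 to 5.65). Of the 5 targets measured at 10 CPM or more, TIPARP was 2.25-fold higher (1.85 to 2.73), SLC7A5 1.34-fold (1.31 to 1.37), CYP2S1 1.34-fold (1.23 to 1.45) and NQO1 1.09-fold (1.06 to 1.13), and EREG was 1.19-fold lower (1.11 to 1.28). Their median log2 ratio was 0.41. ALDH3A1 had a ratio of 0.957 (0.633 to 1.44) and ABCG2 had 21 reads with DMF and 9 with indole. In the IDO1 line, CYP1A1 had 29 reads with DMF and 24 with indole, a ratio of 0.987 (0.550 to 1.76), and CYP1B1 had 38 and 41, a ratio of 1.29 (0.807 to 2.06). AHRR there had 87 and 31 reads and was 2.35-fold lower with indole (1.55 to 3.67).

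**Figure D1:**
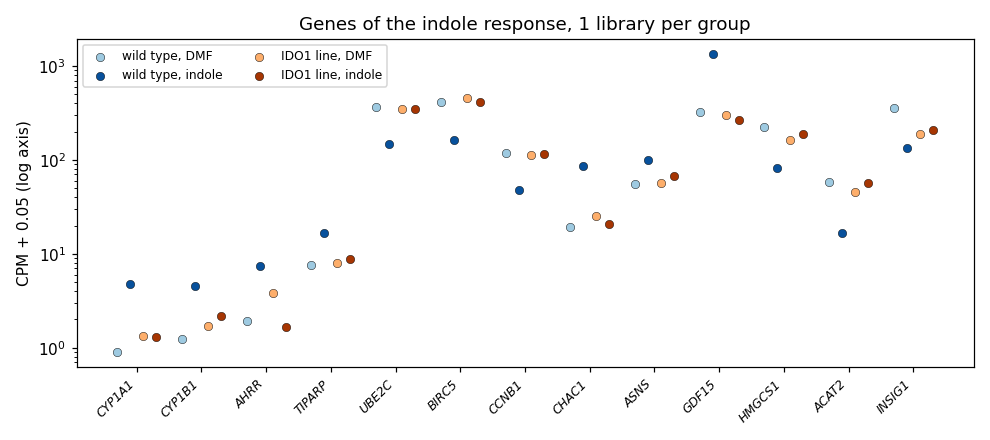
Scaled CPM on a log axis for 13 genes of the indole response, each point being 1 library of the 4 groups, without replicates. For CHAC1, the library of wild type with indole lies at 86.3 CPM and the other libraries at 19.2 to 25.2 CPM.

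Of 8679 genes compared, 252 were at least 2-fold apart, 118 higher and 134 lower with indole. The largest differences upward included the epithelial keratins KRT80, 8.55-fold (6.89 to 10.7), and KRT7, 6.72-fold (5.76 to 7.89), and the neurotrophin receptor NGFR, 5.61-fold (4.98 to 6.33). CDKN2C, a cyclin-dependent kinase inhibitor, was 4.47-fold lower (3.48 to 5.79) and SPC24, a kinetochore component, 3.2-fold lower (2.80 to 3.66). Lower values of HIST1H2BC, TUBA1A, TUBA1B and RPS7 are uncertain because of near-identical copies. With library totals in place of TMM, the median log2 ratio of all genes moved from -0.04 to 0.14 and the split from 118 and 134 to 248 higher and 75 lower. The count was 167 after a trend with abundance, GC content and length was removed. It covers only the 8125 genes with a matched transcript, which include 226 of the 252.

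The library of wild type with indole stood apart from the other 3. The first principal component carried 73.0% of the variance, with a score of 32.6 for that library and scores of -3.69, -13.6 and -15.3 for the others. The groups described above therefore rest on a single library that differs from all others.

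**Figure D2:**
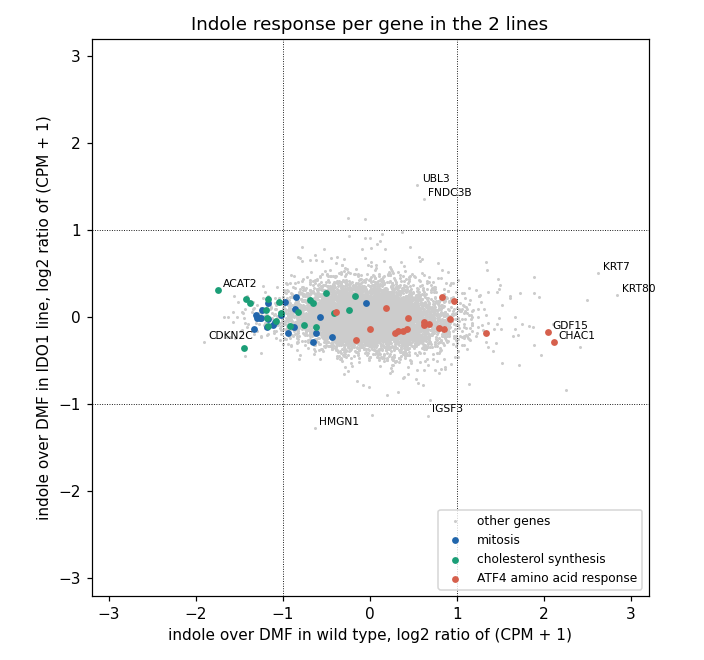
Log2 ratio of indole over DMF, from CPM plus 1, in wild type (horizontal) and in the IDO1 line (vertical) for genes with at least 10 CPM in a library, each point being a gene coloured by list. The mitosis list has a median of -1.09 in wild type and -0.01 in the IDO1 line.

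The next comparison asked how the IDO1 line responds to indole. Of 8523 genes compared, 7 were at least 2-fold apart. UBL3, a membrane-anchored ubiquitin-fold protein, was 3.21-fold higher (2.61 to 3.96), FNDC3B 2.63-fold (2.37 to 2.93), the small GTPase NRAS 2.24-fold (2.08 to 2.42) and DNTTIP1 2.32-fold (1.96 to 2.75). HMGN1, a nucleosome-binding protein, was 2.44-fold lower (2.30 to 2.60), IGSF3 2.24-fold (2.0 to 2.51) and MORC4 2.34-fold (1.92 to 2.85). Of 26 lists, 8 stood apart, all by small amounts, where lists of unrelated genes would give 1.3. The cytosolic tRNA synthetase list had a median of 0.13, the heat shock list 0.14, nuclear OXPHOS 0.11, ribosome biogenesis 0.09, cholesterol synthesis 0.08 and proteasome 0.08. The ATF4 list had a median of -0.13 and the metallothionein list -0.23, with MT2A, a metal-binding protein, 1.43-fold lower (1.41 to 1.45).

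The 2 indole responses were then set against each other. The difference of the log2 ratios was at least 1 for 420 of 8845 genes, 231 of them higher and 189 lower in the IDO1 line than in wild type, or 111 higher and 371 lower with library totals. Across genes, which are not independent replicates, the responses had a Pearson correlation of -0.0997 and a Spearman correlation of -0.111. Of 253 genes at least 2-fold apart in wild type among these genes, 120 had the same direction in the IDO1 line (47.4%) and 0 were also at least 2-fold apart there. BIRC5 was 1.10-fold lower with indole in the IDO1 line (1.07 to 1.13), KRT80 1.22-fold higher (0.972 to 1.54) and GDF15 1.12-fold lower (1.08 to 1.17). The difference between the responses was not tested, as no group had replicates.

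An additive fit over both lines asked which genes moved with indole in both. With edgeR's quasi-likelihood test, 0 of 13122 genes passed the adjusted threshold. There were 448 genes at an unadjusted p under 0.05, and the smallest adjusted p was 0.509, for KRT7. DESeq2 also gave 0 genes, with 129 at an unadjusted p under 0.05. Adjusted over the list alone, 1 member of each of 3 lists rose, among them the NRF2 and interferon lists. Camera with a preset correlation called 11 of 28 lists, led by mitosis and cholesterol synthesis on the lower side, and with an estimated correlation it called 0, the smallest adjusted p being 0.899. With library totals 6 genes passed, with no filter on low counts 10, and with at least 10 CPM in 2 libraries 5, among them FNDC3B, KRT7, NGFR and UBL3.

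**Figure D3:**
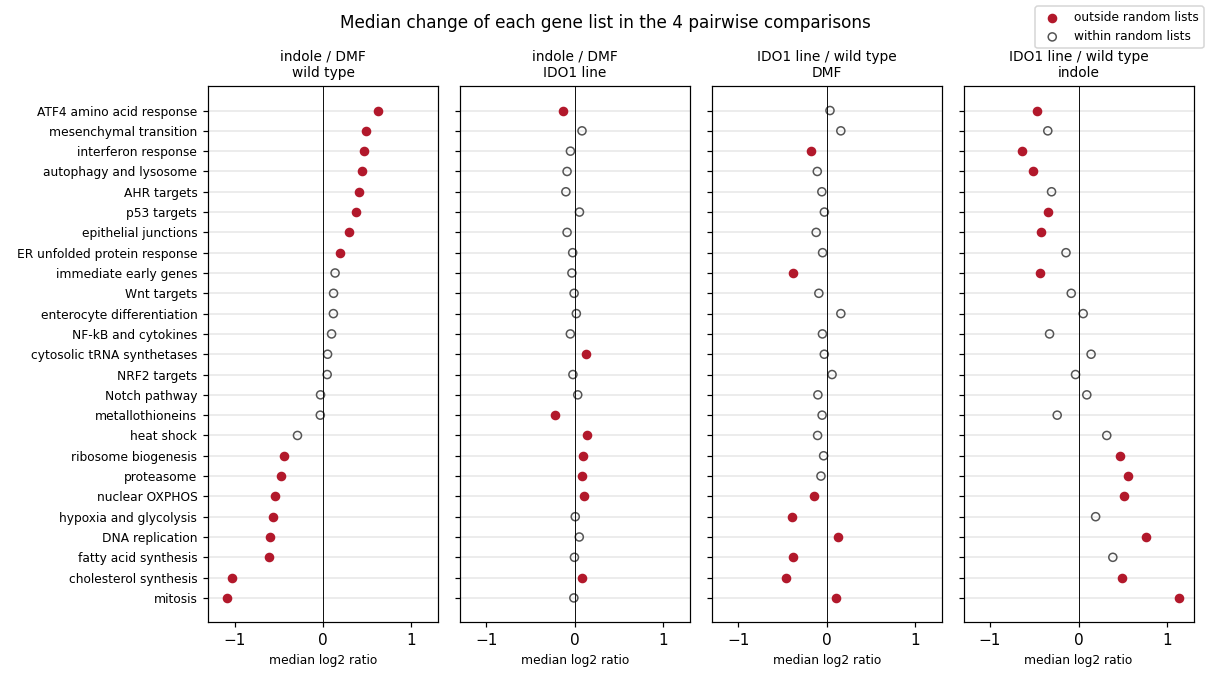
Median log2 ratio in the 4 pairwise comparisons of each list with at least 3 measured genes for indole in wild type, 1 library per group. Filled points are lists that stood apart from 10000 matched random lists. The tryptophan metabolism list had 2 measured genes there and is not shown. Mitosis lies at -1.09 for indole in wild type and at 1.14 for the IDO1 line over wild type in indole, and both use the library of wild type with indole.

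The comparison of the lines in DMF asked what IDO1 overexpression changes without indole. Besides IDO1, the IDO1 line had reads of genes with 0 or 1 read in wild type, and lower levels of the immediate early genes FOS and EGR1. UCHL1, a ubiquitin hydrolase of neurons, was at least 115-fold higher, the metalloprotease ADAMTS1 at least 96.9-fold and the homeobox gene HOXD13 at least 84.2-fold, each from 0 reads in wild type. IRS4, an insulin receptor substrate, went from 1 to 360 reads (336-fold, 59.8 to 13290). VIM, the mesenchymal intermediate filament vimentin, was 13.0-fold higher (10.5 to 16.3) and SPARC, a matrix protein, 12.4-fold (8.18 to 19.6). FOS and EGR1, both transcription factors, were 3.34-fold (2.58 to 4.38) and 2.33-fold (2.22 to 2.45) lower. UBL3 and FNDC3B, the 2 genes with the largest ratios upward with indole in the IDO1 line, were 3.17-fold (2.59 to 3.9) and 2.87-fold (2.59 to 3.19) lower in DMF, and both values use the library of the IDO1 line with DMF.

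Cholesterol synthesis genes had a median log2 ratio of -0.46 in DMF over 21 genes, with 1 above 0. INSIG1, a sterol-regulated ER protein, was 1.87-fold lower (1.80 to 1.94). Fatty acid synthesis had a median of -0.38, hypoxia and glycolysis -0.39, immediate early genes -0.38, interferon response -0.18 and nuclear OXPHOS -0.14, the last 2 being -0.09 and -0.04 with library totals. Tryptophan metabolism had a median of 2.09 over 4 genes, which include IDO1 and IDO2. With a minimum of 1 CPM, 9 genes of that list entered, its median was 0.06 and it no longer stood apart. DNA replication and mitosis had medians of 0.12 and 0.10, or 0.22 and 0.20 with library totals. Of 26 lists, 9 stood apart, where lists of unrelated genes would give 1.3. Of 8500 genes, 38 were at least 2-fold apart, 24 higher and 14 lower. A minimum of 1 CPM gave 236, 211 higher and 25 lower, and a minimum of 50 CPM gave 12, 5 higher and 7 lower.

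In indole, the IDO1 line had higher mitosis genes than wild type, with a median log2 ratio of 1.14, all 22 above 0 and 14 at least 2-fold higher. DLGAP5, a mitotic spindle protein, was 2.46-fold higher (2.31 to 2.63). DNA replication had a median of 0.76, proteasome 0.56, nuclear OXPHOS 0.52, cholesterol synthesis 0.49 and ribosome biogenesis 0.47. The interferon list had a median of -0.64, autophagy and lysosome -0.52, ATF4 -0.47, immediate early genes -0.44, epithelial junctions -0.42 and p53 targets -0.34. Tryptophan metabolism had a median of 2.03, or 0.27 with a minimum of 1 CPM, where it no longer stood apart. NGFR was 9.65-fold lower (8.25 to 11.4) and GDF15 5.01-fold lower (4.87 to 5.17). Of 8765 genes, 395 were at least 2-fold apart, 200 higher and 195 lower, or 147 and 274 with library totals. This comparison shares the library of wild type with indole with the first one, and 31 genes were at least 2-fold apart between the IDO1 line with indole and wild type with DMF.

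An additive fit over both treatments asked which genes differed with the line in both. By edgeR's quasi-likelihood test, 322 of 13122 genes passed, 267 rising and 55 falling in the IDO1 line. All 322 had the same direction in both treatments, which the fit largely requires, as a gene that differs between treatments tests as noisier. Of the genes that rose, 201 had 3 or fewer reads in both wild type libraries. VIM rose by a log2 fold change of 4.01 (SE 0.271, adjusted p 3.2e-11) and SPARC by 3.40 (SE 0.331, adjusted p 3.4e-08), each higher in both treatments. IDO1, IDO2, UCHL1, IRS4, ADAMTS1, HOXD13 and CADM1, a cell adhesion molecule, had at most 2 reads in a wild type library and rose. Among the genes that fell were SAT1, a polyamine acetyltransferase, with -1.63 (SE 0.258, adjusted p 0.000117), the cytokine IL32 with -1.55 (SE 0.302, adjusted p 0.00154), and the siderophore-binding LCN2 with -1.52 (SE 0.296, adjusted p 0.00160). NGFR had -1.86 (SE 0.393, adjusted p 0.00417), with log2 ratios of -0.38 in DMF and -3.14 in indole.

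By list, 3 of 9 tested genes of tryptophan metabolism rose, namely IDO1, IDO2 and QPRT, an enzyme of NAD synthesis from quinolinate, and the count adjusted over the list alone was also 3. IDO1 is the overexpressed gene itself and IDO2 may share its reads, which leaves QPRT alone. QPRT had 0 and 3 reads in wild type and 130 and 145 in the IDO1 line. On the mesenchymal list, 6 of 12 genes rose (VIM, SPARC, FN1, ZEB2, MMP2 and CDH2) and 1 fell, and adjusted over the list alone 7 rose and 2 fell. On the Notch list, HEY1, a target of the pathway, rose alone of 14 genes, and FOS and JUNB fell on the immediate early list of 13. Adjusted over the list alone, 5 immediate early genes fell, as did 4 interferon, 3 epithelial junction, 2 p53 and 1 ATF4 genes, lists of which 0 to 2 members fell over all genes. IL32, NDRG1 and CD44 each fell alone on the cytokine, hypoxia and Wnt lists, and CA2 rose alone on the enterocyte list. HEY1, CD44, CA2 and the mesenchymal genes beyond the 4 that the rule allows were chosen after their values were seen, because they passed. Of 10 AHR targets, 0 passed. Camera called 10 of 28 lists with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.854, and fry called 0.

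Some genes known as markers of embryonic kidney cell lines were higher in the IDO1 line in both treatments. On a list of 33 such genes, drawn up after the largest differences but not these genes' values had been seen, 9 of 25 detected genes were at least 2-fold higher in both treatments and 16 were not, against 319 of 13598 detected genes in all (2.35%). CDH2, 1 of the 9, is also on the mesenchymal list, so its value may have been known. Detected means at least 10 reads in any library, and 16 of the 33 reached that in wild type. The rest of the 25 entered only through the IDO1 libraries, which favours a high share. Of the 16 listed genes with 3 or fewer reads in both wild type libraries, 8 had at least 10 reads in both IDO1 libraries, against 203 of 6761 other such genes (3.0%). DESeq2 called 85 genes for the line, 73 rising and 12 falling, and a fit restricted to genes with at least 10 CPM in 2 libraries called 74, 26 rising and 48 falling, of which 56 were among the 322.

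**Figure D4:**
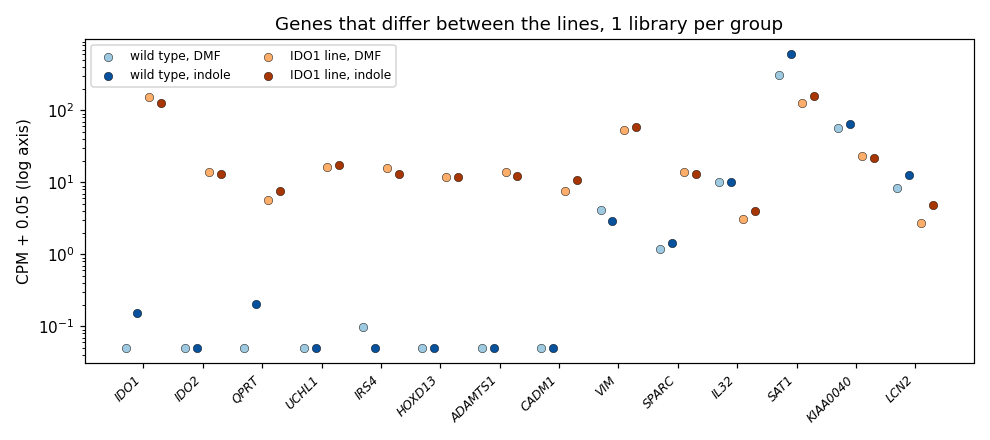
Scaled CPM on a log axis for 14 genes that differed between the lines, each point being 1 library of the 4 groups, without replicates. VIM lies at 4.14 and 2.84 CPM in wild type and at 53.7 and 58.5 CPM in the IDO1 line.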

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

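Among the tests below, the ones on whether indole acted in the IDO1 line and on other cells in that line were chosen after the result was seen. Those on a trend and on counting noise were chosen after the pattern they concern was seen, with bounds written before the tests' own values were known.

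Several groups went one way with indole in wild type and the other way in the IDO1 line, which is a difference between groups that was not tested, as each group has 1 library. The difference of median log2 ratios (IDO1 line minus wild type) was -0.75 for the ATF4 list, 1.11 for cholesterol synthesis, 0.53 for ribosome biogenesis, 0.65 for nuclear OXPHOS and 0.55 for the proteasome. In the same order, the medians in the IDO1 line itself were only -0.13, 0.08, 0.09, 0.11 and 0.08. Most of each difference was thus the wild type value. With a pseudocount of 5, ribosome biogenesis no longer stood apart in wild type. Of single genes, AHRR differed by -2.40, FGF9 by -1.90, IGSF3 by -1.79 and LOC100506123 by -3.09. Over 8845 genes, 3 met the rule of at least 2-fold in one line and at least 1.5-fold in the opposite direction in the other, and 3 met it in the same direction. AHRR was under 10 CPM in every library.

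The first pattern is the indole response of 252 genes in wild type against 7 in the IDO1 line. Counting noise alone as the cause is argued against, since 100 draws of libraries with no change gave 0% of the observed count. Counting error is small at 10 CPM or more, so the draws could hardly give another result. They left out PCR and library noise beyond counting, which stays open. A trend with abundance, GC content and transcript length cannot be told apart as part of the cause, because 54.9% of the 2-fold genes with a transcript remained 2-fold after it was removed, between its bounds. It explained 18.4% of the variance in wild type and 6.07% in the IDO1 line. Over genes with a transcript, removal shrank the medians of mitosis (-1.09 to -0.91), cholesterol synthesis (-1.02 to -0.83) and DNA replication (-0.60 to -0.47). Those of nuclear OXPHOS (-0.53 to -0.34), proteasome (-0.47 to -0.30) and ribosome biogenesis (-0.44 to -0.21) shrank as well. The ATF4 median went from 0.62 to 0.69. Whether indole acted in the library labelled IDO1 line with indole cannot be told apart from a line that responds less, since genes 2-fold apart in wild type moved there by a median of -0.0133 in the wild type direction, and a fault of the single library of wild type with indole stays open as well; an effect of IDO1 on the response is a further hypothesis that was not tested.

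The second pattern is the set of 267 genes that rose in the IDO1 line. A minority of cells of another type may contribute, as 98.1% of these genes were under 10 CPM in both wild type libraries, but release of silenced genes within HCT116 cells, or selection of a clone, would give such values too and was not tested. Cells resembling embryonic kidney lines are a candidate source. On the first list, whose values had not been seen except perhaps that of CDH2, 36% of detected genes were higher, between the bounds. On a second list that includes genes picked after their values were seen, 65.4% were higher, which decides nothing. Of the first list, 16 of 33 genes had at least 10 reads in a wild type library, so HCT116 cells express part of it. The rest of its 25 detected genes were detected only through the IDO1 libraries, which favours a high share. On the second list, IRS4 and UCHL1 had at most 1 read in wild type and reached 15.8 and 16.2 CPM in DMF. Leukocytes, fibroblasts, endothelial cells, hepatocytes and erythroid cells are argued against, as 0% of their markers were higher. For fibroblasts this rests on their own list, of which 3 genes were detected. On the mesenchymal list, 7 of 12 detected genes were higher, among them VIM, FN1 and SPARC.

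The third pattern is the set of 55 genes that fell in the IDO1 line. DESeq2 gave 12 falling genes, the fit without a treatment term 7, and the fit with no filter on low counts 113. The median fall of the 55 genes in DMF was -0.70 on the log2 scale and -1.07 over both treatments, but the genes were chosen for falling, so this median alone decides nothing. Added cells that supply a minority of the RNA cannot lower a gene by more than 2-fold. RNA per cell was not measured, so this bounds a share of RNA, not of cells. In DMF, 25.5% of the genes (14) were lower by more than 2-fold, counting error included. In indole 42 were, where the wild type library stands apart, but only 8 in both treatments. Cells with a minority of the RNA are not the whole cause for these 8 unless the libraries differ by more than counting error, while for the other genes they stay open. A minority of cells that supplies more of the RNA would lower every gene it lacks by more than 2-fold. Of all 8500 genes compared in DMF, 14 were at least 2-fold lower in the IDO1 line. This argues against such cells, unless they resembled HCT116 cells in nearly all genes, which was not tested. Change within the HCT116 cells, through IDO1 or through selection of the line, also stays open and may account for the falls, but was not tested.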

How the results depend on the processing

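Among the alternatives, removal of a trend, the count of passing genes with at least 10 CPM in a library, and the DMF libraries alone were chosen after seeing the data. Of 69 recomputed counts of the main comparisons, 45 were within 1.5 times the main value and 24 moved. Of 309 list medians, 279 kept their sign and side of the random lists' limits, 21 changed sign without standing apart, 4 came to stand apart, 3 no longer did and 2 reversed. Of the values of named genes, 53 moved beyond counting error and 0 changed sign. A pseudocount of 5 gave 149 genes for indole in wild type, 25 and 240 for the lines in DMF and indole, and 245 for the difference of responses. A minimum of 50 CPM gave 118, 12, 177 and 189 for these, and 3 for indole in the IDO1 line; a minimum of 1 CPM gave 14 for the latter, 236 and 756 for the lines and 702 for the difference. These minimums change how many low genes enter. Removal of the trend gave 167 genes for indole in wild type, 124 of them shared, over genes with a matched transcript, which 226 of the 252 had. For the line effect over both treatments, DESeq2 gave 85 (73 rising, 12 falling), at least 10 CPM in 2 libraries 74 (26 and 48), no treatment term 208 (201 and 7), the genes passing with at least 10 CPM in a library 69, and the DMF libraries alone a 2-fold count of 38. For the indole effect, library totals gave 6, no filter 10 and at least 10 CPM in 2 libraries 5. Camera with an estimated correlation gave 0 lists for line and 0 for indole. The mesenchymal list reversed to -0.0948 in wild type and to 0.81 for the lines in indole with a minimum of 1 CPM, when more of its genes entered. The cause of the other moves was not tested. No paired analysis was possible because the columns carry no replicate numbers, though each additive fit blocks on the other factor. Leaving out a library would leave 0 residual degrees of freedom, and the alternatives meant for several columns per sample were not run. Depth limits low genes: the floor of 3 reads is 0.131 to 0.157 CPM.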

Other observations

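The lists that did not stand apart in wild type with indole included Wnt targets, with a median log2 ratio of 0.12 over 9 genes, NRF2 targets with 0.05 over 17, Notch with -0.03 over 9 (0.15 with library totals), NF-kB and cytokines with 0.10 over 7, and immediate early genes with 0.14 over 9. Cytosolic tRNA synthetases had 0.05 over 20 genes (0.23 with library totals, where they stood apart) and enterocyte genes 0.12 over 3. The heat shock list had a median of -0.29 and metallothioneins -0.03 (0.14 with library totals). EGR1 was the only immediate early gene at least 2-fold lower. The secretory and mucin list had 0 genes at 10 CPM or more and the PXR list 1.

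Leukocyte, and hepatocyte and erythroid markers had 0 genes at 10 CPM or more in wild type with indole or DMF, fibroblast and endothelial markers 1 each. With at least 10 reads in a library, 4 leukocyte, 3 fibroblast, 2 endothelial and 1 hepatocyte or erythroid marker were detected, and 0 of them were at least 2-fold higher in both comparisons of the lines.

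Of the genes with 3 or fewer reads in both libraries of one line and at least 30 in both of the other, 88 were present in the IDO1 line alone and 0 in wild type alone, sex-linked genes left out. Among 87 such genes past the test, without IDO1, the ratio of indole to DMF within the IDO1 line had an SD of 0.293 on the log2 scale, against 0.258 from counting error. Both the test and the minimum of 30 reads favour genes with similar levels in these 2 libraries, so the small spread decides nothing.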
